A study of Mus musculus with 2 samples.

How the data were processed

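Gene expression was measured on Affymetrix arrays in haematopoietic stem cells (HSC) sorted from mouse bone marrow by flow cytometry after a short culture. Per the labels, 1 sample held primitive HSC and 1 sample held maturing HSC, and neither was treated. The sorted surface phenotypes are not given in the sources used here. Per the labels' protocols, RNA was reverse transcribed from the poly(A) tail, amplified by PCR, passed over a size fractionation column and cloned in a lambda phage vector. The inserts of each library, tagged with a T7 promoter, were then transcribed into biotinylated cRNA for hybridisation. Each array therefore reports the composition of a cloned cDNA library, and PCR amplification, size selection and cloning can each change the share of a transcript.

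The deposited values are signal intensities on a linear scale, made with MAS5 per the submitters' processing notes, whose version is not given in the sources used here. MAS5 combines the probe pairs of a probe set into 1 intensity and scales the array. The 2% trimmed mean over all probe sets was 1000.6 on the primitive array and 1000.4 on the maturing array, so the deposited intensities had been scaled to the same mean. Detection calls were not used here. Such scaling sets the average intensity equal by construction, so a difference in total RNA per cell cannot be seen.

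The table held 22690 probe sets, of which 64 were controls. In the platform annotation, 20380 probe sets had 1 gene symbol, 691 had several and the remaining non-control probe sets were not listed with a symbol. Symbols were checked through Entrez identifiers against RefSeq for 20351 probe sets, and 0 changed. No gene was named from a probe set with several symbols, and the 2246 non-control probe sets without a single symbol were left out of gene counts. For each of 12393 genes, the probe set with the highest mean intensity was used.

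Both arrays were rescaled to the same 2% trimmed mean, which changed almost nothing. Intensities under 441.0, the pooled median of the non-control probe sets, were set to that floor. Ratios are log2 of primitive over maturing. A gene with 1 side at the floor has a ratio that is only a lower bound on the difference, and a gene with both sides at the floor was not measured. Genes at least 4-fold apart were counted in each direction. With 1 array per group there are no replicates, so no test between the populations was possible and no p-value is given. The number of arrays limits the precision.

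A total of 40 gene lists covering translation, metabolism, protein and RNA processing, the cell cycle, stem cell and lineage genes, signalling and chromatin was fixed before the data were examined, together with the floor, the threshold and the alternative settings. For each list with at least 5 measured genes the median log2 ratio was taken, with genes at the floor on 1 array entered at their bound, and with an exact binomial 95% interval over genes. That median was placed among the medians of 10000 random lists of equal size matched on mean signal in 20 bins. A list under percentile 2.5 or over percentile 97.5 was said to lie outside the random range. The percentile describes these 2 libraries and carries no biological error, and genes of a list are not independent.

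The genes named in the text followed a rule fixed at the same time. These were the 12 largest ratios in each direction among genes above the floor on both arrays and the 6 largest bounds in each direction, in both cases only where all measured probe sets of the gene went the same way. To these were added up to 4 members of each described list with the largest ratio or bound. The brightest neutrophil and monocyte genes and 16 stem cell and lineage genes were also named. Of these 16, Ly6a was not analysed here, and a further item is not reported here.

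The steps were tested on simulated data made from the 12393 genes with a noise SD of 0.82 on the log2 scale, the SD between probe sets of a gene. Over 20 simulations without any change, a mean of 39.0 genes passed 4-fold as higher and 37.0 as lower. The noise was drawn independently for each probe set, with no error shared between genes or from making the libraries. These counts therefore do not tell how many genes would pass between replicate libraries. Of 108 genes changed 4-fold, 54.6% were recovered, and of 92 genes changed 8-fold, 94.6%. A list of 30 genes shifted by log2 1 gave a median of 0.93 at percentile 100.0, and 7 of 200 unshifted lists (3.5%) lay outside the random range. The unshifted lists were themselves random draws, so their share checks only the steps. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

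Alternatives were the values as deposited, a median ratio of 0, quantile normalization, lowess with a fraction of 0.3, floors at percentiles 25 and 75, 2-fold and 8-fold thresholds, the median of a gene's probe sets, and leaving out probe sets that can bind several transcripts. Scaling to the hybridisation controls and random lists matched on signal and genomic span were added after the data had been seen. Proteins of 7 lists were also sorted by size, as small (up to 32 kDa) or large (from 39 kDa), from textbook sizes after the list medians had been seen.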

Results

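Transcripts of primitive and maturing HSC from mouse bone marrow were compared on 1 array each. Intensities ran from 2.9 to 212983.1 on the primitive array, with a median of 425.4, and from 1.7 to 136594.0 on the maturing array, with a median of 454.8. The 100 brightest probe sets carried 26.3% of the primitive signal and 18.6% of the maturing signal. Of 12393 genes, 8852 were measured. There were no replicates, so each value below describes this pair of libraries and no difference could be set against a spread between samples.

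The comparison asked how the transcripts of primitive HSC differ from those of maturing HSC. By the medians of gene lists, genes of DNA replication, protein folding and splicing were lower in primitive HSC. However, small members of the replication (6 genes) and splicing (10 genes) lists had medians of 0.0001 and 0.18. Large members (32 and 19 genes) had -1.06 and -0.55. Both differences lay inside the range of random splits of the same members (percentiles 84.5 and 87.6). The protein folding list was not split by size, and its median of -0.77 lay inside the interval of large proteins of 7 other lists (-0.88 to -0.25). Many of those large proteins came from the replication, splicing and translation factor lists, which were below the random range themselves. The comparison therefore cannot tell protein size from list membership. Lists for mitosis, nucleotide synthesis and lymphoid-primed progenitors also lay below the random range, with intervals that included 0, and mitosis came inside it over genes above the floor on both arrays (percentile 4.38) and nucleotide synthesis after lowess (3.11). Lists for ribosomal proteins, mitochondrial ribosomal proteins, respiratory complex I and macrophages and dendritic cells lay above the random range, as did a combined list of T and natural killer cell genes whose interval included 0. The ribosomal lists came inside it after lowess (70.7 and 89.0) and quantile normalization (68.8 and 90.0), and scaling to the hybridisation controls left the ribosomal and complex I medians between 0.03 and 0.09 and turned the mitochondrial ribosomal (-0.39), macrophage (-0.16) and T and natural killer (-0.11) medians negative. The replication helicase gene Mcm7 was 20.4-fold higher in maturing HSC, and the stem cell surface gene Procr was 6.1-fold higher in primitive HSC.

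At the 4-fold threshold, 305 genes were higher in primitive HSC and 415 were higher in maturing HSC, 8.1% of the measured genes, but the balance turned to 165 and 126 with the floor at percentile 75 and to 66 and 60 at 8-fold. Of the 305, 199 were above the floor on both arrays and 106 were bounds, and of the 415, 193 were above the floor on both arrays and 222 were bounds. Genes higher in primitive HSC made up 42.4% of the 720, and 6.9% when the arrays were scaled to the hybridisation controls, which moved the median log2 ratio of genes above the floor on both arrays from 0.09 to -0.68. Of the 720, 324 had more than 1 measured probe set, and all of a gene's probe sets went the same way in 230 of them (71.0%). Among 2439 such genes under 4-fold that share was 53.6%. A total of 5908 genes (66.7%) lay within 2-fold. Log2 signals correlated across the 5525 genes above the floor on both arrays with r = 0.73, where genes are not independent replicates. The SD between probe sets of a gene was 0.82 on the log2 scale over 1318 genes, against an SD of 1.07 of the ratios, so ratios near 2-fold are of the size of the spread between probe sets.

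**Figure D1:**
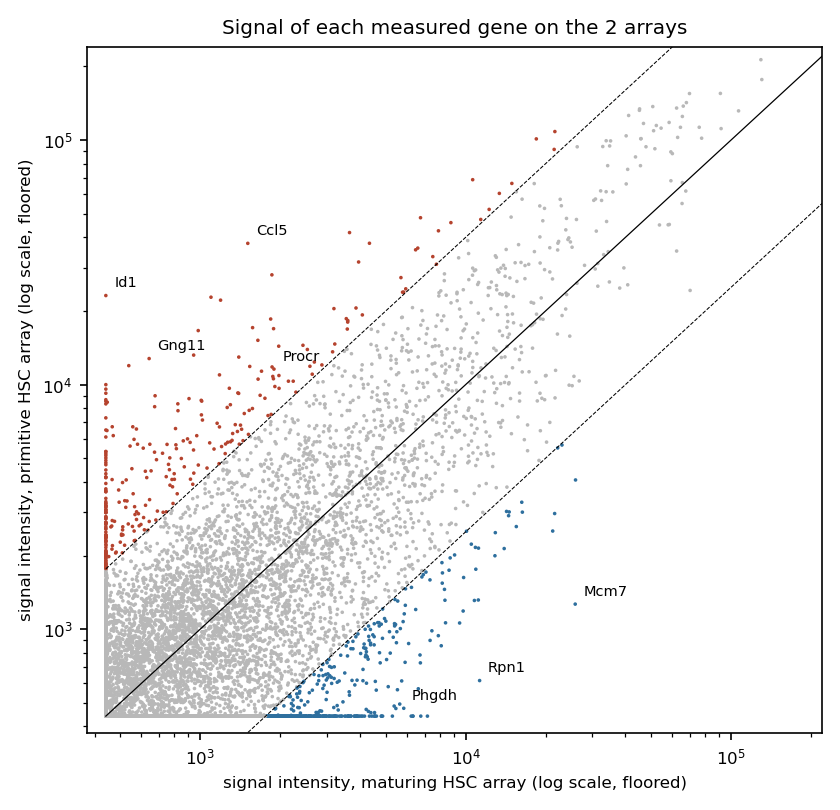
Signal intensity of the 8852 measured genes on the maturing array (x axis) and the primitive array (y axis), both on log scales with values under 441.0 drawn at that floor. Each point is a gene, the solid line is equality, dashed lines mark 4-fold, red points are the 305 genes higher in primitive HSC and blue points the 415 higher in maturing HSC.

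Among genes above the floor on both arrays with agreeing probe sets, the chemokine gene Ccl5 had the largest ratio toward primitive HSC, with 37795 against 1511 and a log2 ratio of 4.64. It was followed by Klk8 (22.2-fold), the RNA polymerase III subunit gene Polr3d (20.7-fold), the G protein subunit gene Gng11 (19.9-fold), Sra1 (19.0-fold) and Abca7 (18.6-fold). Pop5, Use1, Capn3, Vps36, Mrps18a and Pradc1 were between 13.2-fold and 16.9-fold higher in primitive HSC. In the other direction, Mcm7 read 1266 against 25865, and Rpn1, a subunit of the oligosaccharyltransferase, was 18.3-fold higher in maturing HSC. The serine synthesis gene Phgdh was 12.3-fold higher in maturing HSC, the splicing regulator gene Sfpq 11.6-fold, the adenosine kinase gene Adk 11.5-fold and Cdc5l 11.4-fold. Rfc2, Rap1a, Ide, Zfp386, Cnot6 and Cnot7 were between 9.32-fold and 11.1-fold higher in maturing HSC.

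Genes at the floor on 1 array gave only bounds. Id1, an inhibitor of basic helix-loop-helix factors, was at least 52.4-fold higher in primitive HSC. Glrx2, Rnaseh1, Hsdl2, the T cell receptor component gene Cd3d and Fam50a were at least 19.4-fold higher there. The adhesion receptor gene Cd44 was at least 14.4-fold higher in maturing HSC. Coa5, Ankrd33b, Pttg1ip, Tax1bp1 and Ipo5 were at least 10.9-fold higher in maturing HSC.

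Of 39 lists, 6 lay above and 11 below the random range, where chance gives 2.0 outside. Of 21 measured small-subunit ribosomal protein genes, 19 were higher in primitive HSC, with a median log2 ratio of 1.07 (95% interval 0.77 to 1.57, percentile 99.0). Rps9 had a log2 ratio of 3.20, Rps10 2.45, Fau 2.32 and Rps18 2.19. Of 21 measured large-subunit genes, 20 were higher in primitive HSC, with a median of 1.04 (0.72 to 1.52, percentile 98.1) and Rpl37a at 3.52, Rpl14 at 3.30, Rpl37 at 2.68 and Rplp2 at 1.62. Most of these genes were bright, and the tenth of genes with the highest signal had a median of 0.53. After lowess the medians of the 2 lists were 0.13 and 0.32 at percentiles 70.7 and 89.0, within the random range. Control probe sets for 18S ribosomal RNA were higher on the primitive array by a median log2 ratio of 1.10. The hybridisation controls were higher there as well, by 0.97, so the 18S value does not bear on ribosomes alone.

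Genes for mitochondrial ribosomal proteins had a median of 0.59 (0.19 to 0.78, percentile 99.96), with 46 of 68 higher in primitive HSC. Mrps18a (3.73), Mrps6 (2.43) and Mrpl17 (2.20) were higher in primitive HSC, and Mrps18c was at least 8.63-fold higher in maturing HSC. Respiratory complex I, the entry point of electrons from NADH, had a median of 1.01 (0.30 to 1.52, percentile 99.8), with 28 of 32 genes higher in primitive HSC. Ndufa12 (2.86), Ndufb5 (2.43) and Ndufs3 (2.36) were higher in primitive HSC, and Ndufv1 was at least 9.84-fold higher in maturing HSC. The median of complexes III and IV, cytochrome c and ATP synthase was 0.66 (0.22 to 0.97) but within the random range at percentile 84.0. It fell to 0.16 after lowess and 0.18 after quantile normalization. Scaling to the hybridisation controls turned the mitochondrial ribosomal median to -0.39 at percentile 99.8 and lowered that of complex I from 1.01 to 0.03, and those of the large and small ribosomal subunits from 1.04 and 1.07 to 0.06 and 0.09.

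Of 40 measured DNA replication and S phase genes, 29 were higher in maturing HSC, 11 of them at least 4-fold, and 1 was at least 4-fold higher in primitive HSC. The median was -0.95 (-1.63 to -0.06, percentile 0.0). Besides Mcm7 (-4.35) and the clamp loader gene Rfc2 (-3.47), Mcm6 stood at -2.67 and the DNA ligase gene Lig1 at -2.52. Mitosis genes had a median of -0.62 (-1.24 to 0.09, percentile 0.01), and the proliferation marker gene Mki67 (-2.03) and the topoisomerase gene Top2a (-2.19) were lower in primitive HSC. Nusap1 was at least 4.99-fold higher in maturing HSC and Cenpa at least 4.51-fold higher in primitive HSC. The mitosis percentile was 4.38 over genes above the floor on both arrays, with a median of -0.26, and 8.95 with the floor at percentile 75, with a median of -0.27. Nucleotide and one-carbon synthesis had a median of -0.71 (-1.52 to 0.42, percentile 0.53), which became -0.52 at percentile 3.11 after lowess and -0.46 at 2.55 with the floor at percentile 75, with Phgdh at -3.62 and Psat1, Ctps and Umps at least 8.39-fold, 8.19-fold and 5.34-fold higher in maturing HSC.

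Heat shock protein and chaperonin genes were higher in maturing HSC for 26 of 29 members, with a median of -0.77 (-1.57 to -0.40, percentile 0.0), which was -1.16 after quantile normalization. The chaperonin subunit gene Cct6a stood at -3.08, the disulfide isomerase genes Pdia3 and Pdia6 at -2.41 and -2.34, and Hspa4 at -2.16. Splicing factors and hnRNPs had a median of -0.55 (-0.92 to -0.0007, percentile 0.06), with Sf3b3 and Hnrnpl at least 8.73-fold and 6.17-fold higher in maturing HSC and Hnrnph1 and Sf3b2 at -2.56 and -2.21. Translation factors had a median of -0.37 (-0.93 to 0.29, percentile 0.12), which was -0.84 after lowess, -0.72 with the floor at percentile 25, -0.62 after quantile normalization, -0.55 with the median of probe sets and -0.23 without probe sets that can bind several transcripts, with Eif1a (-2.44), Gspt1 (-2.23) and Etf1 (-2.09) lower in primitive HSC. Eif5b stood at 2.09, with its other probe set at -0.29. Aminoacyl-tRNA synthetases had a median of -0.73 (-1.55 to 0.08, percentile 1.33), which became percentile 7.93 over genes above the floor on both arrays. Hars, Rars and Vars were at least 4.32-fold, 3.89-fold and 3.31-fold higher in maturing HSC, and Iars was 3.39-fold higher in primitive HSC. The citric acid cycle had a median of -0.49 (-1.20 to -0.16, percentile 0.82), or -0.76 with the floor at percentile 25, and came inside the random range at percentile 2.54 over genes above the floor on both arrays, with Cs at -2.60, Dlat at -2.02, Idh3a at -2.28 with probe sets from -2.28 to 0.32, and Aco1 at least 10.9-fold higher in maturing HSC.

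Protein size went with the ratio inside 7 lists. These lists hold small and large proteins, include respiratory complex I and leave out both kinds of ribosomal protein. In them, 112 genes for small proteins had a median log2 ratio of 0.73 (0.54 to 0.93) and 114 genes for large proteins -0.58 (-0.88 to -0.25). The 2 pools draw unequally on the lists, with 27 small and 3 large genes from complex I and 6 and 32 from replication. Their gap therefore also holds differences between lists. Within single lists, small minus large ran from 0.73 to 1.87. Small proteins had the higher median in 7 of 7 lists, but only 2 lists on their own lay above the range of random splits. Among proteasome subunits the medians were 0.71 and -0.65, while the whole list had 0.54 (-0.41 to 0.82, percentile 87.8). Large DNA replication proteins had a median of -1.06, and large proteins of the remaining lists -0.53. The heat shock, synthetase and citric acid cycle lists were not split by size. Their medians of -0.77, -0.73 and -0.49 lay inside the interval of the large proteins. Among those 114 proteins, 32 were from the replication, 21 from the translation factor and 19 from the splicing list. These lists were below the random range themselves, so the interval cannot tell size from list membership. Across genes, the median was 0.34 in the shortest of 5 classes of genomic span and -0.03 in the longest.

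**Figure D2:**
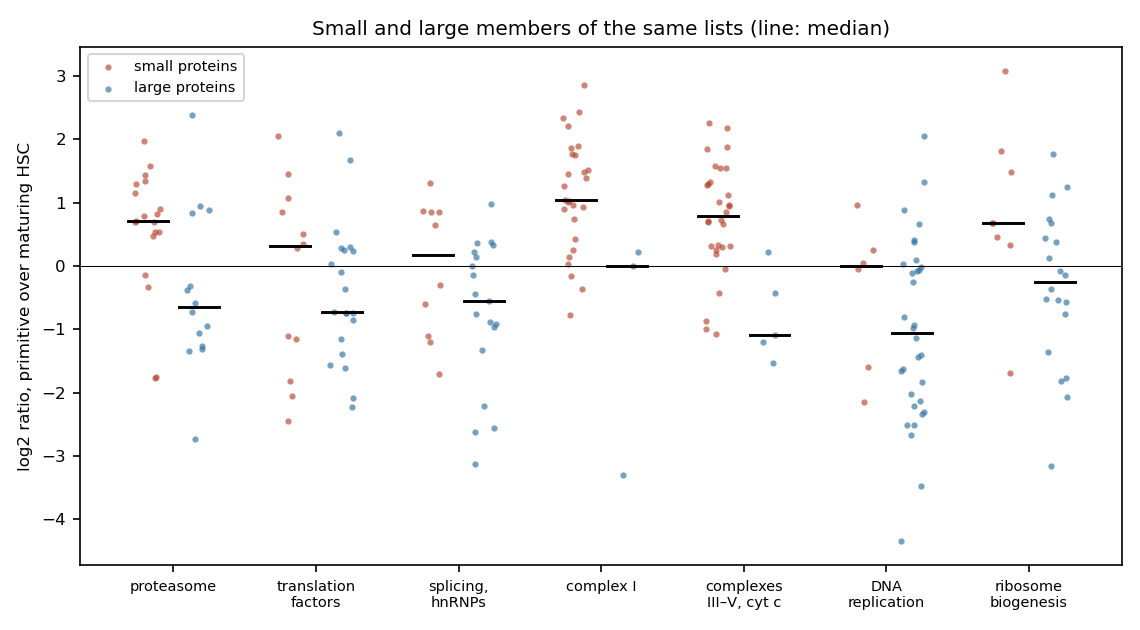
Log2 ratio of primitive over maturing HSC (y axis) for single genes of 7 lists (x axis), split into genes for small (red) and large (blue) proteins, with black lines at the medians. Points are spread sideways at random. The small proteins have the higher median in each list, for example 0.71 against -0.65 in the proteasome.

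Stem cell surface genes had a median of -0.02 (-0.41 to 0.51, percentile 31.95). Procr, the endothelial protein C receptor gene, read 11571 in primitive and 1896 in maturing HSC, and the transporter gene Abcg2 was at least 3.84-fold higher in primitive HSC. Cd44 and the integrin gene Itga6 (-1.96) were lower in primitive HSC. The stem cell factor receptor gene Kit had a log2 ratio of -0.41, Cd34 -0.91, Thy1 0.56 and Slamf1 0.24, and the Slamf1 probe sets disagreed in direction. Stem cell transcription factors and regulators had a median of -0.44 (-0.90 to 0.60, percentile 1.72), and percentile 2.96 over genes above the floor on both arrays, within the random range. Nfe2 stood at 3.16, and Cbfb, Sox4 and Myb stood at -2.71, -2.63 and -2.44. Gata2 had a ratio of 0.19, Mecom was at least 1.11-fold higher in primitive HSC and Meis1 at least 2.72-fold higher in maturing HSC.

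Multipotent and lymphoid-primed progenitor genes had the lowest list median in the main setting, -1.24 (-1.67 to 0.70, percentile 0.01). After quantile normalization heat shock genes were lower, at -1.16 against -1.15. The cytokine receptor gene Flt3 was at least 5.16-fold and Satb1 at least 5.22-fold higher in maturing HSC, and Cd53 (-2.32) and Cd48 (-1.41) were lower in primitive HSC. Il7r was at least 6.79-fold higher in primitive HSC, with a second probe set at -0.40. B cell genes had a median of -0.78 (-1.45 to 0.30, percentile 0.37), with Jchain at -2.03 and Spib at -1.23, Vpreb3 at least 2.73-fold higher in maturing HSC, and 8 probe sets of Ighm from -2.71 to 1.38. The B cell percentile was 6.86 with the floor at percentile 25, and the median was -0.34 with the floor at percentile 75 and -0.41 with the median of probe sets. Neutrophil and monocyte genes had a median of -0.20 (-1.10 to 0.68, percentile 6.05), and percentile 1.72 with span matched. The granule gene Mpo was at least 5.87-fold and Csf3r at least 5.84-fold higher in maturing HSC, and Ms4a3 (-2.66) and Chil3 (-2.21) were lower in primitive HSC. The brightest members of this list went the other way. S100a8 read 46743 in primitive and 19527 in maturing HSC, Lyz1 35511 and 22210, Camp 27725 and 14077, and Lyz2 23502 and 13453.

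T and natural killer cell genes had a median of 0.71 (-0.01 to 1.71, percentile 99.8) over 19 measured genes. Besides Ccl5 and Cd3d, Gata3 was at least 4.68-fold and Klrd1 at least 4.33-fold higher in primitive HSC, while Cd3e was at the floor on both arrays. In sets chosen after the values had been seen, 8 measured T cell genes had a median of -0.06 (-0.87 to 1.18) and 8 natural killer cell genes 1.22 (-0.33 to 4.64). Cd3d, Gata3, Cd7 (a bound of 0.71) and Tbx21 (a bound of -0.01) were in neither set, and of these only Tbx21 was not higher in primitive HSC. The percentile of the whole list was 95.7 over the 6 genes above the floor on both arrays and 91.0 with the floor at percentile 25. Macrophage and dendritic cell genes had a median of 0.69 (0.04 to 1.28, percentile 99.6), with Apoe, Cd86, Bst2 and Msr1 at least 3.55-fold, 3.08-fold, 2.67-fold and 2.59-fold higher in primitive HSC, and percentile 97.1 over genes above the floor on both arrays. The macrophage median was 0.33 with the floor at percentile 75. Both medians turned negative, to -0.11 and -0.16, when the arrays were scaled to the hybridisation controls. Megakaryocyte genes had a median of -0.18 (-0.83 to 0.41, percentile 24.2), with Gng11 (4.31) and Tbxas1 (1.52) higher in primitive HSC, Gp9 at least 4.13-fold higher there, and Thbs1 (-2.30) and Pf4 (-0.82) lower. Erythroid genes had a median of -0.21 (-0.39 to 0.66), mast cell, basophil and eosinophil genes 0.39 (-1.41 to 0.97) and stromal and endothelial genes -0.06 (-0.62 to 0.58), all within the random range. The mast cell list median was -0.04 after quantile normalization and -0.06 over genes above the floor on both arrays. The globin gene Hba-a1 was at the floor on both arrays.

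**Figure D3:**
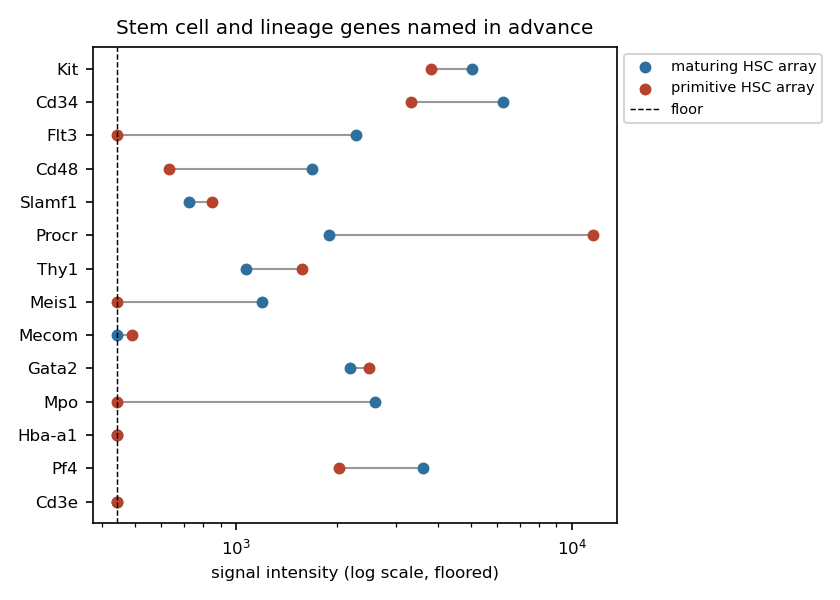
Signal intensity (x axis, log scale) of stem cell and lineage genes chosen in advance on the maturing (blue) and primitive (red) arrays, with values under the dashed line, the floor of 441.0, drawn at the floor. Procr lies far to the right on the primitive array, and Flt3, Meis1 and Mpo are at the floor there.

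Metabolic lists within the random range were glycolysis (median -0.06, -0.63 to 0.30), fatty acid oxidation (-0.51, -1.42 to 0.08), cholesterol synthesis (-0.21, -1.19 to 0.75) and antioxidant enzymes (0.48, -0.43 to 0.95), although antioxidant enzymes reached percentile 98.1 over genes above the floor on both arrays and fatty acid oxidation 2.43 under hybridisation control scaling. Ribosome biogenesis and nucleolar proteins had a median of 0.20 (-0.53 to 0.67), cytoskeleton genes -0.12 (-0.76 to 0.31) and chromatin genes -0.02 (-0.84 to 0.34). With the median of each gene's probe sets, chromatin genes had a median of -0.66 at percentile 0.28, outside the random range. Cell cycle inhibitors and quiescence regulators had a median of -0.0008 (-0.28 to 0.83) and D-type cyclins with their kinases and the Myc network 0.10 (-0.36 to 0.69).

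**Figure D4:**
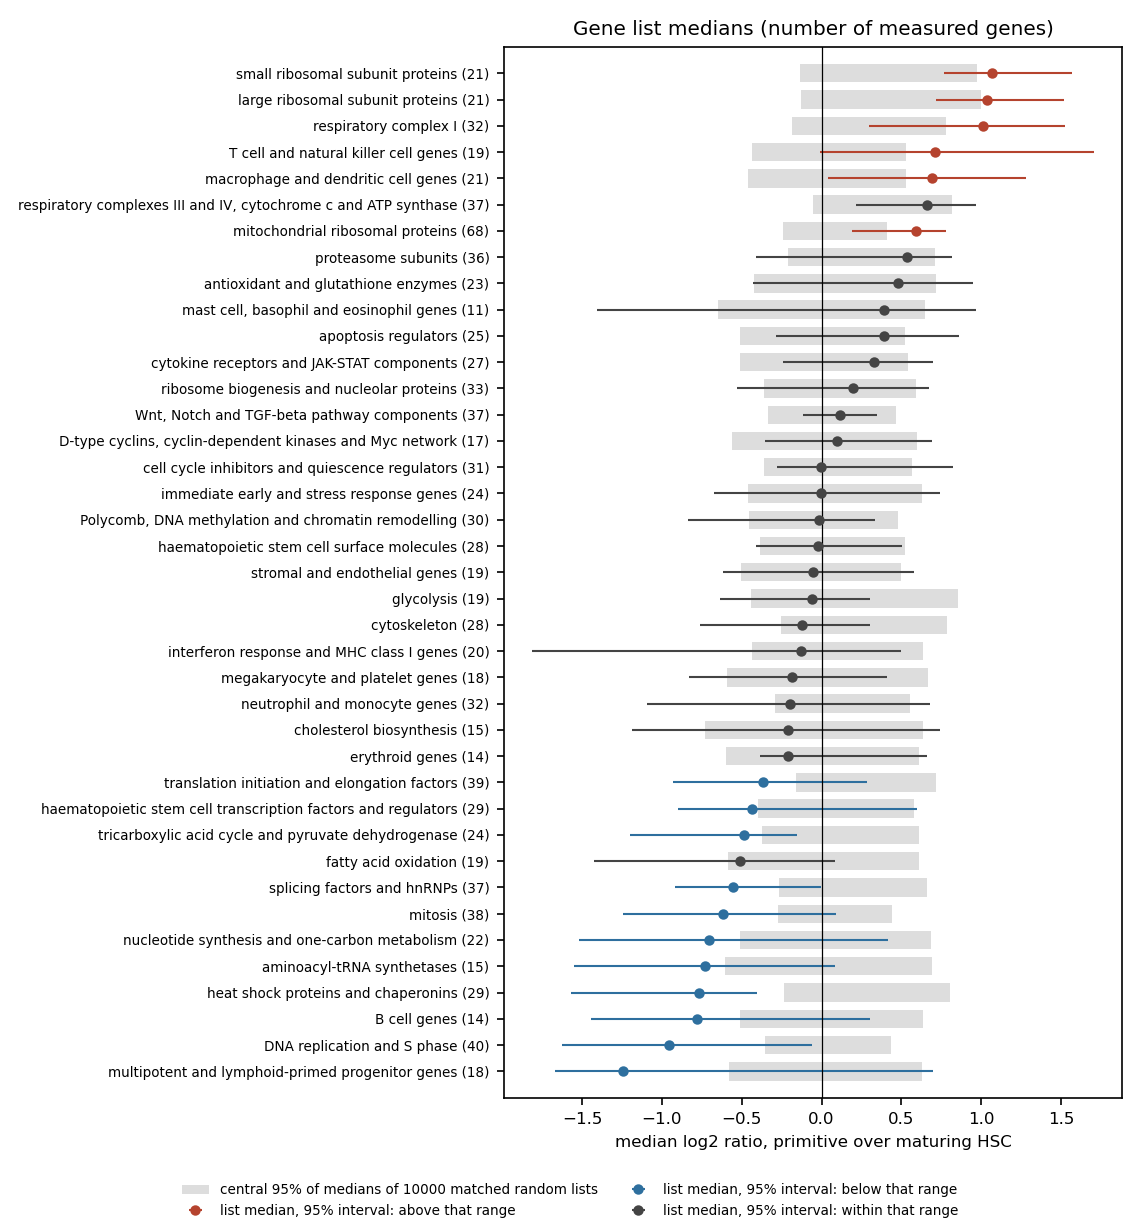
Median log2 ratio of primitive over maturing HSC (x axis) for 39 gene lists (y axis, with the number of measured genes), with 95% intervals over genes. Grey bars span the central 95% of medians of 10000 random lists matched on signal. Red marks the 6 lists above and blue the 11 lists below that range, and under scaling to the hybridisation controls the mitochondrial ribosomal, T and natural killer cell, and macrophage lists had negative medians.

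The 18 hybridisation control probe sets were all brighter on the primitive array, by a median log2 ratio of 0.97 (0.52 to 1.89). The ratio of 3' to 5' signal was 2.07 for Actb in primitive HSC and 1.61 in maturing HSC, and 0.71 and 0.70 for Gapdh. Scaling to the hybridisation controls lowers a ratio measured on both arrays by 0.97, so that ratios between 0 and 0.97 change sign. Under it the medians of the 11 lists below the random range ran from -2.04 to -1.13.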

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

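Lowess was a planned setting, while the tests of size and span, translation, T cells and natural killer cells were chosen after the results had been seen, and the T cell, translation, ribosomal and replication tests were revised after their values had been seen. The first forms counted T cell genes at the floor as 0, which gave an upper bound of 0.13, and drew random lists from the comparison proteins alone, which gave percentile 99.8 for ribosomal and 0.05 for replication proteins. They were replaced because the floor fixes the former and the latter leave out the spread of the tested genes, and the revised forms exclude less. The translation test first used proteins of all sizes and excluded a rise of translation genes, but it mixed protein size with function, so it was limited to small proteins. Span-matched lists were added last to the replication test and to the test of small against large members, which until then had both fitted a shift toward short transcripts. Control probe sets lie outside the gene comparison, and a pair of signals stood out there. The 18S ribosomal RNA probe sets differed by a median log2 ratio of 1.10 and the hybridisation controls by 0.97, both brighter on the primitive array.

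The first pattern weighed is that the ribosomal, mitochondrial ribosomal and complex I lists were higher in primitive HSC. Across all sizes, 87 translation factors, synthetases and nucleolar proteins had a median of -0.10 (-0.72 to 0.25), against 1.06 (0.84 to 1.32) for 42 ribosomal proteins. The translation factor and synthetase lists were below the random range, at -0.37 and -0.73. These values argue against a rise of ribosomal size across translation genes of all sizes, but they mix protein size with function. For small proteins a coordinated rise stays open, since the 20 small ones among the 87 had 0.48 (-1.11 to 1.07), which overlaps. A difference of scale that depends on signal is argued against for the mitochondrial ribosomal and complex I lists by their medians. After lowess, which removes such a difference, these were 0.59 and 0.80, against 0.59 and 1.01 before. The lists also stayed at percentile 99.9 or higher after lowess, but the random lists were already matched on signal, so this adds little. For the large and small ribosomal lists a difference of scale stays open. Lowess took their medians from 1.04 and 1.07 to 0.32 and 0.13, at percentiles 89.0 and 70.7, inside the random range. Whether a shift of the primitive library toward short transcripts may account for the lists stays open. Small minus large members of 7 lists, which include complex I itself and leave out both kinds of ribosomal protein, gave a difference of 1.30. That was above 99.95% of random splits made within the lists and pooled, the highest of which was 1.43. The lists give unequal numbers of small and large members, so part of the difference can come from the lists and not from size. On their own, 2 lists lay above the random range. The mitochondrial ribosomal (98.4) and complex I (99.7) lists stayed above the random range with genomic span matched. Genomic span includes introns and is not transcript length, so these percentiles cannot count against such a shift. The mitochondrial ribosomal median of 0.59 was not above that of the small proteins, 0.73, to which complex I gave 27 genes. Whether the ribosomal proteins exceed such a shift is open, because their median was 0.34 above that of other small proteins (percentile 99.3 of shuffled memberships) but their percentiles with genomic span matched were 90.6 and 93.0. The shuffled memberships were not matched on signal.

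The second pattern is the lower level of DNA replication genes in primitive HSC. Whether the same shift toward short transcripts may account for it stays open. Large replication proteins differed from other large proteins by a median of -0.53, inside the random range at percentile 4.14 of shuffled memberships. Those other large proteins include 21 translation factors and 19 splicing genes. Their lists were also below the random range, so this difference cannot tell size from list membership. The replication list stayed at percentile 0.0 among random lists matched on signal and genomic span. Because span is not transcript length, that percentile cannot exclude the shift. A difference between the cells themselves, named by the design, stays open and untested with 1 array per population.

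The third pattern is the higher T and natural killer cell list in primitive HSC. Whether T cells may have been among the sorted cells stays open, since 8 measured T cell genes had a median of -0.06 (-0.87 to 1.18) and 8 more were at the floor on both arrays. Left out of this set were Cd3d and also Gata3 and Cd7, with bounds of 2.23 and 0.71 toward primitive HSC. Natural killer cells could be a source, with a median of 1.22 (-0.33 to 4.64) over 8 genes, Ccl5 at 37795 against 1511 and Nkg7 at 6299 against 7933, but the interval includes the median of small proteins, 0.73. Of these 8 genes, 1 (Nkg7) is also in the neutrophil list, and the gate that would remove such cells is not given in the sources used here.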

How the results depend on the processing

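The hybridisation control scaling and the span-matched lists were chosen after seeing the data. The values as deposited were almost those of the main setting, and a median ratio of 0 shifts ratios by a near constant. Neither could move a percentile much, so lists that stayed outside the random range in these settings add little. Of 17 lists outside the random range, 7 stayed outside it in the 11 other settings, and over all settings 156 of their percentiles stayed outside and 31 came inside, while 4 lists inside the range lay outside it in some setting. These were antioxidant enzymes (98.1 over genes above the floor on both arrays), neutrophil and monocyte genes (1.72 with span matched), chromatin genes (0.28 with the median of probe sets) and fatty acid oxidation (2.43 with hybridisation control scaling). In all, 35 list medians left their intervals, 29 of them with hybridisation control scaling. The cause was not tested, except that floors and thresholds change which genes are counted. Counts (primitive, maturing) were 1385 and 1559 at 2-fold, 66 and 60 at 8-fold, 761 and 998 with the floor at percentile 25, 165 and 126 (56.7% primitive) at percentile 75, and 91 and 1231 with hybridisation control scaling. Lists below the range numbered 7 over genes above the floor on both arrays, and with the floor at percentile 75 there were 3 above and 6 below. Over genes above the floor on both arrays, percentiles were 96.5 for large ribosomal, 7.93 for synthetases, 2.54 for the citric acid cycle, 4.38 for mitosis, 2.96 for stem cell transcription factors, 95.7 for T and natural killer and 97.1 for macrophage genes. With span matched they were 90.6 for large and 93.0 for small ribosomal proteins and 3.22 for synthetases. Quantile normalization gave 90.0, 68.8 and 4.78 for large and small ribosomal proteins and transcription factors, and lowess 89.0, 70.7 and 4.05, with 3.11 for nucleotide synthesis. The floor at percentile 25 gave 6.86 for B cell, 91.0 for T and natural killer and 96.6 for macrophage genes. The floor at percentile 75 gave 95.6 and 97.4 for large and small ribosomal proteins, 5.46 for synthetases, 2.55 for nucleotide synthesis, 8.95 for mitosis, 5.28 for transcription factors, 11.7 for B cell and 95.8 for macrophage genes. The median of probe sets gave 4.15 for B cell genes. Hybridisation control scaling gave 5.11 for transcription factors and 5.98 for B cell genes, and turned the medians of mitochondrial ribosomal (-0.39), T and natural killer (-0.11) and macrophage genes (-0.16) negative. Matching on transcript length was not run, as lengths were not given. Leaving out arrays and other splits need more than 1 array per group. No paired analysis was possible because each group had 1 sample and replicate numbers only follow accession order. Genes near the floor have the least precise ratios, and the SD between probe sets was 1.06 with the floor at percentile 25 and 0.69 at percentile 75.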

Other observations

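Signalling lists fixed before the data were examined held large single differences with list medians inside the random range. The Wnt, Notch and TGF-beta list had a median of 0.11 (-0.12 to 0.35), with the inhibitor genes Id1 and Id2 at least 52.4-fold and 6.82-fold higher in primitive HSC, and the TGF-beta mediator gene Smad4 and the Notch mediator gene Rbpj at least 8.29-fold and 4.3-fold higher in maturing HSC. Interferon and MHC class I genes had a median of -0.13 (-1.81 to 0.50), with Gbp2, Gbp3 and Irf9 at least 5.31-fold, 4.7-fold and 4.18-fold and Rsad2 5.08-fold higher in maturing HSC. Immediate early and stress genes had a median of -0.0049 (-0.67 to 0.74), with Ddit3 (2.74), Ier2 (2.01) and Egr3 (1.78) higher in primitive HSC and Nfil3 (-1.99) lower. Apoptosis regulators had a median of 0.39 (-0.28 to 0.86) and cytokine receptors with JAK-STAT components 0.33 (-0.24 to 0.70).

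Among cell cycle genes within the random range, Cdk4 and the D-type cyclin gene Ccnd3 were 5.08-fold and 4.32-fold higher in maturing HSC. Btg2, an antiproliferative gene, was 5.08-fold higher in primitive HSC, while Ccng2 and Tob1 were at least 6.74-fold and 4.07-fold higher in maturing HSC. The Cdc25a probe sets ran from -2.67 to 2.24.

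The sex-linked list had too few measured genes for a median. Xist read 47798 in primitive and 23978 in maturing HSC, with 3 probe sets from -2.59 to 0.995. Eif2s3y and Uty were at the floor on both arrays, and Kdm5d read 288.8 and 453.7. X-linked genes had a median of 0.04 over 286 genes and autosomal genes 0.07 over 8550.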
